A study of Mus musculus with 18 samples.

How the data were processed

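RNA was measured by sequencing in 18 tumours grown in mice from PB2 cells, a mouse breast cancer cell line. Per the labels, 10 tumours carried the genotype EV and 8 carried p95HER2, a truncated form of the receptor tyrosine kinase HER2, and the mice received a doxycycline diet. Per the labels' protocols, RNA was isolated with a column kit, enriched for mRNA and made into directional libraries. The labels give no batch, sex, age or pairing. The number in the tumour tag of p95HER2 1 lies far below those of all other tumours, which run close together, and the labels do not say why. This tumour was kept, and leaving it out was one of the alternatives. The tags also separate the groups: the other p95HER2 tumours run from P1947 to P1960 and the EV tumours from E1962 to E1974. What the numbers count is not stated. The labels do not state that each tumour came from a separate mouse, so p-values measure the spread between these samples. Replicates were numbered in accession order and the numbers only name a sample.

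The authors deposited raw read counts per Ensembl gene, 1 column per tumour, with no normalization. Per the submitters' processing notes, STAR 2.5, HTSeq 0.6.1 and genome build mm10 were used. The strand option and the annotation release behind the counts are not given in the sources used here, so counts of genes that overlap on opposite strands are uncertain. Reads shared between near-identical paralogs are uncertain as well. A human transgene would map to the mouse genome only in part, and the species of the p95HER2 sequence is not given in the sources used here.

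The table held 54532 genes, of which 22778 had a count of 0 in every library. Symbols were found for 54409 identifiers. Coordinates were taken from a GENCODE annotation of the same genome build, which held 54495 of the identifiers, and are 1-based. Library totals ranged from 35030920 to 38464541 counts in EV tumours and from 32686558 to 34804640 in p95HER2 tumours, so the totals of the groups did not overlap. Group thus ran with tag order as well as with library total, so a difference in handling that followed either cannot be told apart from p95HER2. The most similar pair of libraries still differed by more than sampling noise, and all 18 were kept as separate samples.

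Gene tests used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, libraries were scaled by TMM, and a robust quasi-likelihood F-test compared p95HER2 with EV. All adjusted p-values of single genes are from this edgeR test with Benjamini-Hochberg (BH) adjustment over the genes tested, unless another tool is named, and a gene was called at an adjusted p under 0.05. Log2 fold changes are p95HER2 minus EV, with standard errors (SE). CPM values, counts divided by the TMM-scaled library total, are given as mean ± SD.

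Gene lists were fixed before the data were examined: 16 pathway lists and 15 lists of cell type markers. Each was tested with camera in limma 3.58.1 on voom values, two-sided, with a preset correlation between genes of 0.01 and BH adjustment over the 31 lists. Camera with an estimated correlation and fry were run beside it. The level of a marker list in a tumour was the mean of log2(CPM + 0.5) over its measured members, and levels were compared with a two-sided exact permutation test over all 43758 assignments of the tumours, adjusted by BH over the 15 marker lists.

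Genes to be named were also chosen by a rule fixed before the data were examined. It took Erbb2, Egfr and Erbb3, and the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 1, a symbol that is not a predicted-gene or clone name, and at least 7 of the 8 p95HER2 tumours on the side of the change. It also took the 4 members of smallest adjusted p of each called list and up to 2 of every other list. Genes named outside the rule are said to be so, and 2 genes that the rule took are not reported here.

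Alternatives fixed beforehand were RLE scaling, library totals only, no filter, a filter at 1 CPM, DESeq2 1.42.0, limma voom with quality weights, glmTreat against a fold of 1.5, immune or epithelial marker level as a covariate, each tumour left out in turn, and another pseudocount or scaling for marker levels. Alternatives added after the data were seen were the skeletal muscle level as a covariate, EV 1 and p95HER2 4 left out together, libraries thinned to the smallest total, and removal of chromosome 5 genes. Windows of 10 Mb with at least 20 expressed genes were compared by their median with an exact permutation test, an analysis also added after the data were seen.

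The gene test was tested on simulated counts for p95HER2 against EV, run on 16979 genes. It recovered 20 of 49 genes changed by 1.25-fold, 28 of 48 changed by 1.5-fold, 42 of 49 changed by 2-fold and 44 of 45 changed by 4-fold, and it called 10 of 16506 unchanged genes. The window test recovered 3 of 3 windows shifted by 0.2 on the log2 scale and called 0 of 216 others. Simulated genes were drawn independently of each other, with no shared variation between neighbouring genes and no difference in host cells. These rates may therefore not hold for the real tumours, where neighbouring genes can move together. Counting intervals are exact 95% binomial intervals and cover counting error only. Tables and plots were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.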

Results

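The transcriptomes of 18 tumours grown from PB2 mouse breast cancer cells were compared, 10 labelled EV and 8 labelled p95HER2. The comparison addresses how overexpression of p95HER2, a truncated HER2 receptor, changes gene expression in these tumours. The libraries held 35030920 to 38464541 counts in EV tumours and 32686558 to 34804640 in p95HER2 tumours.

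Reads counted under mouse Erbb2 were 2.33 times as frequent in p95HER2 tumours as in EV tumours. Tumours with p95HER2 also carried Hmga2, Lama3, Dynap and Klk6 mRNA that was scarce in EV tumours. Genes of matrix degradation (Mmp10, Mmp13, Mmp2), HER ligands (Hbegf, Nrg2, Tgfa), the activin subunit Inhba and the laminin subunit Lamb3 rose. Interferon-induced genes such as Oas2, Mx1 and Ifi27l2a fell, as did 10 of 20 macrophage markers, 3 of 20 T cell markers and 4 of 16 markers of cytotoxic cells. The adipocyte genes Plin4, Adipoq and Cfd fell too.

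Erbb2, which encodes HER2 (ENSMUSG00000062312, chromosome 11, 98412470 to 98437716 on the plus strand, mm10), was expressed at 67.9 ± 4.64 CPM in EV tumours (SD, n = 10) and at 158 ± 37.7 CPM in p95HER2 tumours (SD, n = 8). Its log2 fold change was 1.22 (SE 0.10, edgeR quasi-likelihood BH-adjusted p = 2.889e-07), and all 8 p95HER2 tumours lay above the EV median. The lowest p95HER2 tumour had 122 CPM and the highest EV tumour 74.9 CPM. Reads of a human transgene would be counted only in part. The partner receptors gave no call: Egfr was at 88.0 ± 5.53 CPM in EV and 82.4 ± 8.72 CPM in p95HER2 tumours (edgeR BH-adjusted p = 0.301), and Erbb3 at 65.3 ± 5.90 and 60.4 ± 8.93 CPM (edgeR BH-adjusted p = 0.364).

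**Figure D1:**
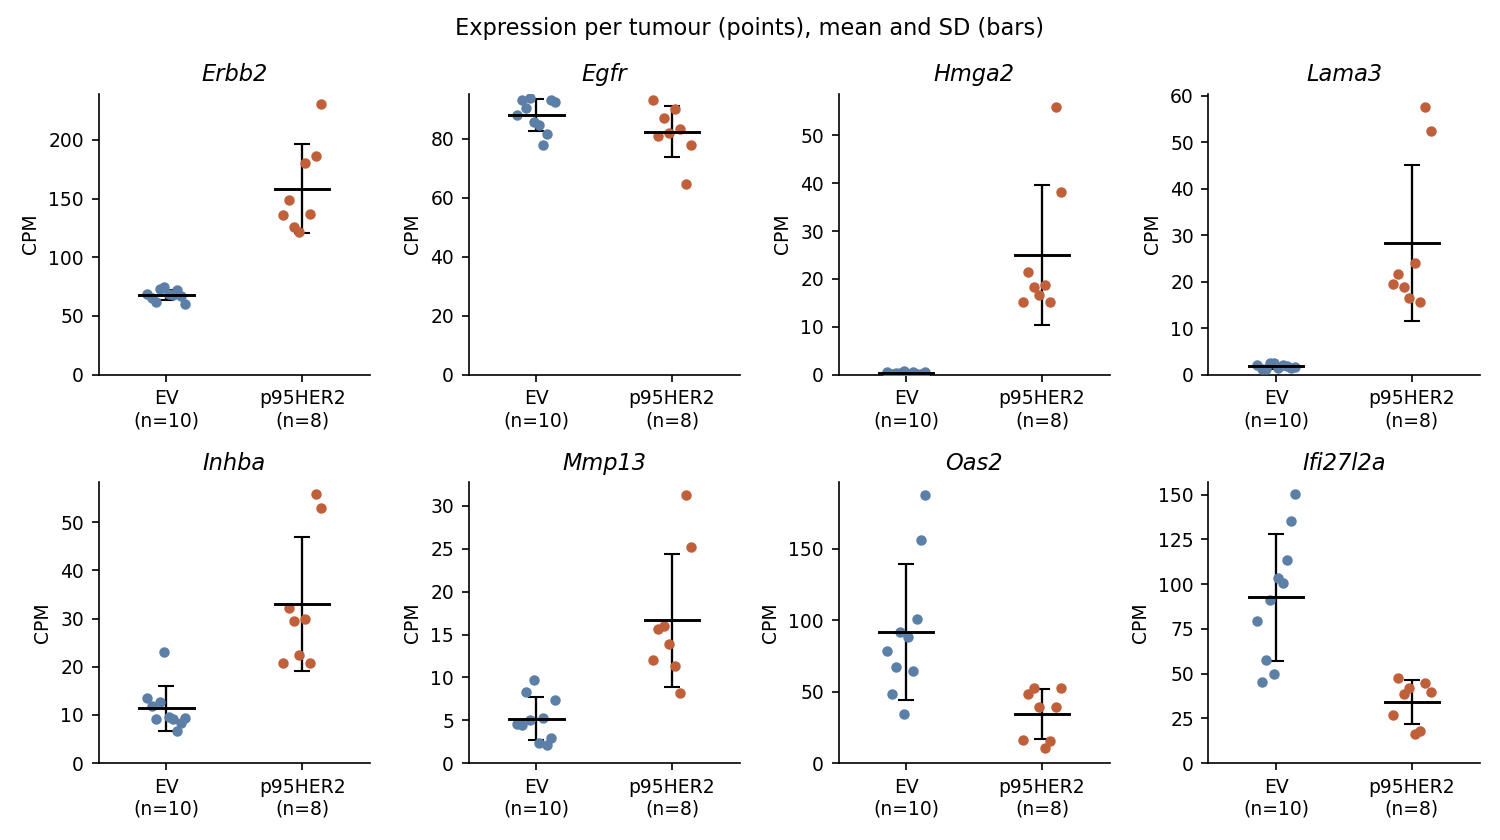
Expression of 8 genes in each tumour, in CPM on a linear axis, for EV (n = 10) and p95HER2 (n = 8); points are tumours, horizontal bars means and error bars SD. Erbb2 lay between 122 and 231 CPM in p95HER2 tumours, above all EV tumours, while the groups overlapped for Egfr.

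Of 17123 genes tested, 1743 changed (10.2%), 981 higher and 762 lower in p95HER2 tumours (edgeR quasi-likelihood, BH-adjusted p under 0.05). Most changes were small: 764 of the higher and 371 of the lower genes differed by less than 1.5-fold, while 86 were higher and 113 lower by at least 2-fold. Before adjustment 4502 genes had p under 0.05, where 856 would be expected by chance. With the immune marker level as a covariate 475 genes were called, and a test against a fold of 1.5 called 52. Leaving out p95HER2 2 lowered the number of lower genes to 489.

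The largest rise by the fitted fold was that of Prl2c3, a member of the prolactin-like gene family whose close paralogs make its counts uncertain. It had 1 count over all EV tumours and 1609 over the p95HER2 tumours, a ratio of 2185 with a 95% counting interval from 392 to 86366. Dynap rose from 0.0380 ± 0.0631 to 7.90 ± 5.02 CPM. Hmga2, a chromatin protein of embryonic tissues (ENSMUSG00000056758, chromosome 10, 120361275 to 120476469), rose from 0.360 ± 0.220 CPM by a factor of 68.8, with a log2 fold change of 6.11 (SE 0.37, edgeR BH-adjusted p = 1.617e-08). The protease Klk6 rose by 5.73 on the log2 scale and Lama3, a laminin subunit of epithelial basement membranes, by 3.96. The neutrophil-attracting chemokine Cxcl5 rose from 0.538 ± 0.439 to 4.64 ± 2.49 CPM, and the kinase gene Prkg2 and the G-protein regulator Rgs8 rose by 2.51 and 2.06 on the log2 scale. All 8 p95HER2 tumours lay above the EV median for each of these genes.

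The largest fall was that of the chloride channel gene Clic6, from 5.11 ± 3.41 CPM in EV to 0.591 ± 0.494 CPM in p95HER2 tumours (log2 fold change -3.10, SE 0.65, edgeR BH-adjusted p = 0.0069). The adipocyte genes Cfd and Plin4 fell by 1.95 and 1.77 on the log2 scale, and Cfd varied widely among EV tumours (12.4 ± 13.6 CPM). The T cell gene Cd2 fell by 1.69 and Gzmb, which encodes granzyme B, by 1.52. Cyp2f2 and the potassium channel gene Kcnk5 fell by 1.58 and 1.54. The interferon-induced gene Ifi27l2a fell from 92.7 ± 35.4 to 34.3 ± 12.2 CPM. The calls of Cd2 and Gzmb were lost without p95HER2 1 or without p95HER2 2, with an edgeR BH-adjusted p of up to 0.0548 for Cd2 and 0.0541 for Gzmb. That of Cfd was lost when any of 11 tumours was left out, with an edgeR BH-adjusted p of up to 0.0794.

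Among HER family receptors and ligands, 4 of 12 measured members rose and none fell, and adjusted over the list alone 5 rose and 2 fell. Beside Erbb2, the ligand genes Hbegf, Nrg2 and Tgfa rose, Hbegf from 11.8 ± 6.84 to 27.5 ± 9.67 CPM and Tgfa by 0.18 on the log2 scale. Of 20 genes induced by ERK signalling or feeding back on it, 4 rose (adjusted over the list alone 7 rose and 1 fell): the AP-1 subunit Fosl1, the ERK inhibitors Spred1 and Spred2, and Etv4. Fosl1 rose by 1.85 on the log2 scale (SE 0.42), the other 3 by 0.20 to 0.27. Of 21 invasion and matrix degradation genes, 6 rose (adjusted over the list alone 8). Mmp10 rose by 3.69, Mmp13 by 1.68 and Mmp2 from 255 ± 61.1 to 417 ± 42.0 CPM, and the adhesion receptor Cd44 rose by 0.37 on the log2 scale. Of 15 TGF-beta response genes, 3 rose, Inhba, Pmepa1 and Ltbp2 (adjusted over the list alone 4 rose and 1 fell). Inhba rose from 11.4 ± 4.62 to 33.1 ± 13.9 CPM, and Ltbp1 did not pass (edgeR BH-adjusted p = 0.0565).

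Of 14 basal epithelial markers, 4 rose (adjusted over the list alone 5), among them Itgb4, Lamb3 and Dsg3. These encode parts of the basement membrane, its anchoring junctions and desmosomes. Itgb4 rose from 150 ± 25.1 to 221 ± 26.6 CPM, while the basal keratin genes Krt5 and Krt14 had edgeR BH-adjusted p = 0.94 and 0.128. Among 5 erythroid markers, Alas2 rose by 0.85 on the log2 scale (1 also when adjusted over the list alone), and 10 single tumours each ended that call when left out (edgeR BH-adjusted p up to 0.0894).

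These 6 lists were called higher by camera with the preset correlation, with BH-adjusted p = 3.52e-05 for invasion, 0.000666 for basal epithelial, 0.00252 for ERK output, 0.0252 for both HER family and erythroid, and 0.0282 for TGF-beta. The HER family list includes Erbb2, whose rise the p95HER2 label itself may bring about, and the list was not tested without it. With an estimated correlation none of the 6 was called (camera adjusted p = 0.418 for each except erythroid, adjusted p = 0.557). The HER family call ended without EV 4 (camera adjusted p = 0.0613), the erythroid call without EV 4 or p95HER2 8, and the TGF-beta call without EV 3, EV 4 or p95HER2 8. With the epithelial marker level as a covariate the HER family, TGF-beta, basal epithelial and erythroid calls ended (camera adjusted p = 0.0549, 0.206, 0.135 and 0.510), with the skeletal muscle level the HER family and erythroid calls (camera adjusted p = 0.0981 and 0.235), and without chromosome 5 genes the HER family call (camera adjusted p = 0.0754).

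**Figure D2:**
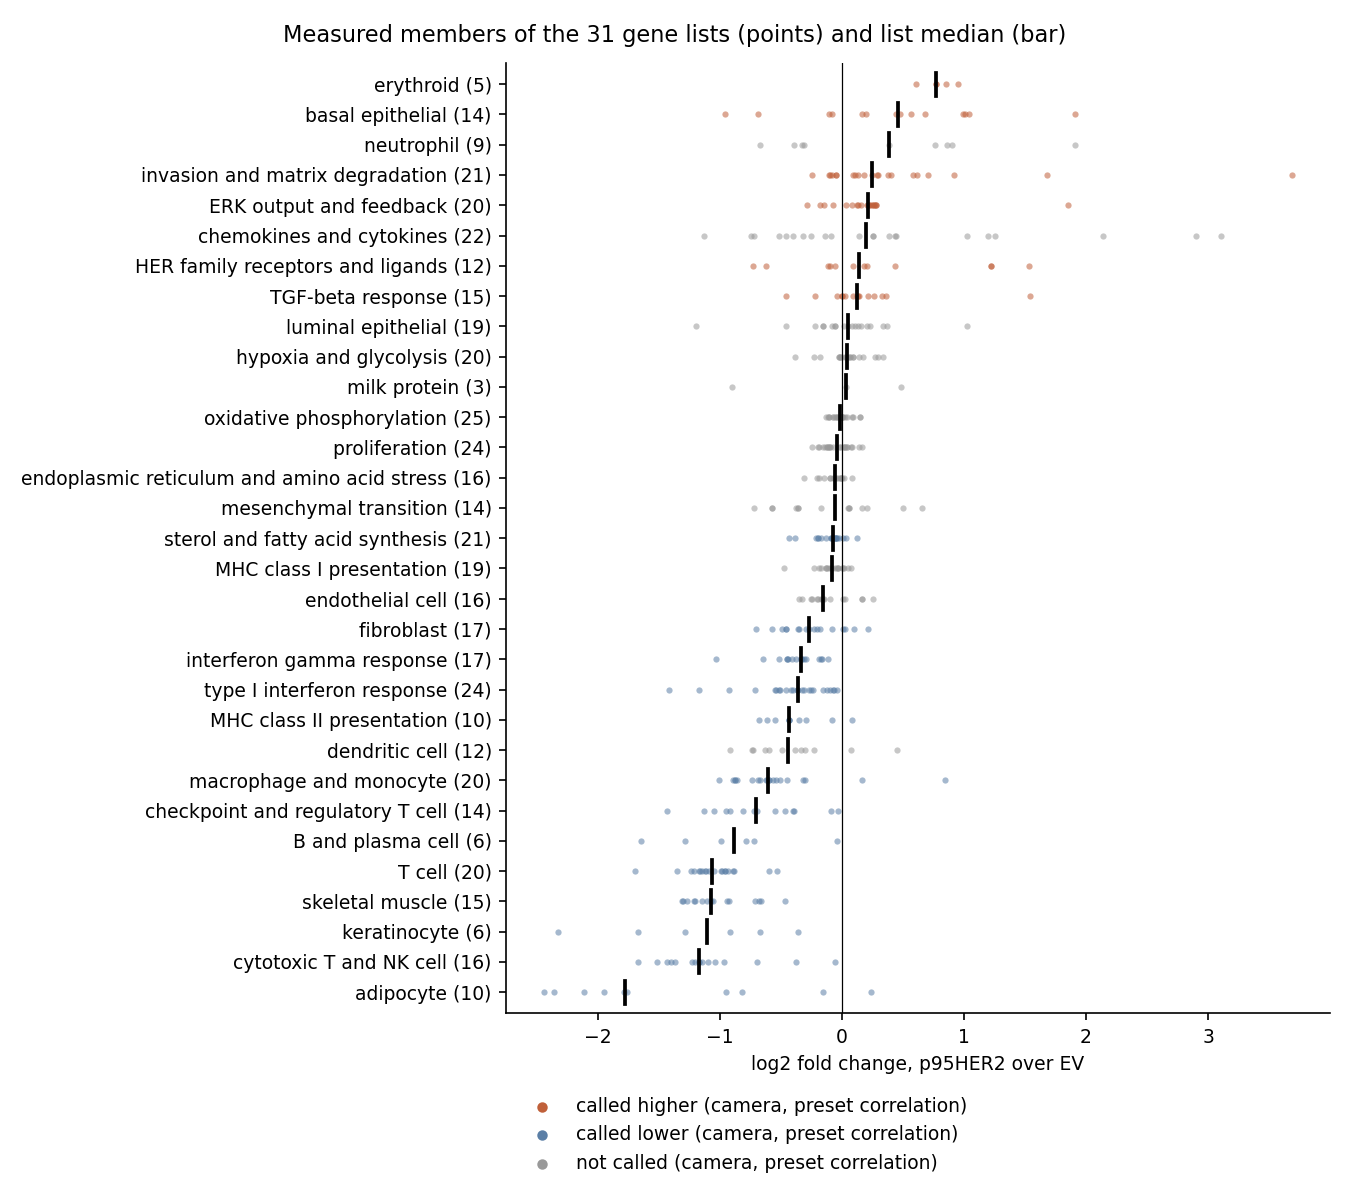
Log2 fold change (horizontal axis) of each measured member of the 31 fixed lists, with the number of members beside each name; points are genes, black bars list medians and colours the camera call with the preset correlation. All 24 type I interferon response genes lay below 0, and the adipocyte list had the lowest median, -1.78.

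Of 24 type I interferon response genes, 5 fell and 24 had a negative log2 fold change (adjusted over the list alone, 12 fell). Oas2 fell from 91.7 ± 47.3 to 34.3 ± 17.5 CPM, Mx1 from 17.9 ± 7.12 to 9.42 ± 2.46 CPM, Oasl1 by 0.51 and Oas1a by 0.72 on the log2 scale. The fifth, Irf7, named after its value was seen, fell by 0.55. The Oas1a call ended when any of 7 tumours was left out (edgeR BH-adjusted p up to 0.069). Oasl1, Oas2 and Oas1a lie between 110 and 130 Mb on chromosome 5, where expression was lower in p95HER2 tumours along the chromosome. Mx1 lies between 90 and 100 Mb on chromosome 16, a stretch that was lower as well. Without chromosome 5 genes the list was still called by camera with the preset correlation, while over all genes it was not called with an estimated correlation (camera adjusted p = 0.476). Removing chromosome 5 genes leaves Mx1 in, and the list was not tested without the genes of all lowered stretches. Of 17 interferon gamma response genes and 10 MHC class II presentation genes, none passed, also when adjusted over the list alone. Their medians were -0.34 and -0.44 on the log2 scale.

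Of 20 macrophage and monocyte markers, 10 fell (adjusted over the list alone, 18 fell and 1 rose). Adgre1, which encodes F4/80, fell by 0.89 on the log2 scale, Lyz2 from 257 ± 41.9 to 169 ± 47.1 CPM, and Ms4a7 by 0.88 on the log2 scale. Of 20 T cell markers, 3 fell, Bcl11b, Cd2 and Cd4, and 19 fell when adjusted over the list alone. Of 16 cytotoxic T and NK cell markers, Prf1, Gzmb, Klrb1c and Ccl5 fell, and 13 fell when adjusted over the list alone. Prf1, which encodes perforin, fell from 1.96 ± 1.27 to 0.611 ± 0.232 CPM. Of 14 checkpoint and regulatory T cell genes, Havcr2, Tox and Ccr8 fell (adjusted over the list alone, 8 fell), and Ctla4 did not pass (edgeR BH-adjusted p = 0.0570). Of 6 measured B and plasma cell markers, Cd22 and Pax5 fell (adjusted over the list alone, 3 fell). The calls of Cd4, Ccl5, Tox, Ccr8, Cd22 and Pax5 each ended in 5 to 11 of the fits with 1 tumour left out (edgeR BH-adjusted p up to 0.0797, for Ccr8).

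Markers of other tissues were lower in the same tumours. Of 10 measured adipocyte markers, 6 fell (adjusted over the list alone, 8), among them Plin4, Adipoq, Cidec and Fabp4, and Adipoq fell by 2.44 on the log2 scale (SE 0.65). Cidec and Fabp4 lost their calls when any of 3 and of 7 tumours was left out (edgeR BH-adjusted p up to 0.0521 and 0.0701). Of 6 measured keratinocyte markers, Krt79 and Sbsn fell (adjusted over the list alone, 4). Of 17 fibroblast markers, Postn fell from 431 ± 113 to 263 ± 56.2 CPM (adjusted over the list alone, 1 fell). None of 15 skeletal muscle markers passed, also when adjusted over the list alone, although all 15 had a negative log2 fold change. None of 21 sterol and fatty acid synthesis genes passed either, and their median was -0.08 on the log2 scale.

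The 13 lists called lower by camera with the preset correlation were led by macrophage (BH-adjusted p = 1.21e-07), T cell (7.42e-07) and type I interferon (2.04e-06), with sterol synthesis the weakest (0.0489). With an estimated correlation none of the 13 was called (camera adjusted p from 0.418 to 0.686). With the immune marker level as a covariate the medians of the interferon gamma and MHC class II lists turned to 0.15 and 0.30, and both lists were called higher (camera adjusted p = 0.00965 and 0.00932). Fits with a covariate used the preset correlation only, while the correlations estimated without it were 0.94 and 0.90 for these lists. The covariate averages T cell, B cell, macrophage, neutrophil and dendritic cell levels, some of which differed between the groups. These calls therefore do not establish a rise. The immune covariate ended the calls of type I interferon (camera adjusted p = 0.322), checkpoint, T cell, cytotoxic, B cell, fibroblast, skeletal muscle and sterol synthesis (camera adjusted p from 0.0727 to 0.529). The skeletal muscle level as a covariate ended the calls of interferon gamma, MHC class II, fibroblast and sterol synthesis (camera adjusted p = 0.351, 0.235, 0.0767 and 0.299) and turned the direction of the skeletal muscle list, which it adjusts for itself. The epithelial level ended those of interferon gamma, MHC class II, skeletal muscle and sterol synthesis (camera adjusted p = 0.303, 0.123, 0.485 and 0.919), removal of chromosome 5 genes those of interferon gamma and sterol synthesis (camera adjusted p = 0.0637 and 0.0684), and scaling by library totals that of sterol synthesis (camera adjusted p = 0.0582). Single tumours ended the calls of interferon gamma (EV 7 or p95HER2 4), MHC class II (p95HER2 1 or 4) and skeletal muscle (p95HER2 4), and any of 11 tumours ended that of sterol synthesis.

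The other 12 lists were not called. Chemokines and cytokines moved both ways: of 22 measured members, 6 rose and 1 fell (adjusted over the list alone, 7 rose and 6 fell). Il1a rose by 2.90 on the log2 scale, and beside Cxcl5 the neutrophil chemokine genes Cxcl1 and Cxcl2 rose by 1.02 and 2.14, as did Ccl20 and Csf3, while Ccl8 fell by 1.13; these 5 were named after their values were seen. Of 9 neutrophil markers S100a8 rose from 8.10 ± 1.82 to 15.1 ± 3.28 CPM and Clec4d fell (adjusted over the list alone, 3 rose and 1 fell), the latter not without EV 2 or without p95HER2 1, 4, 5 or 7. Of 12 dendritic cell markers Batf3 rose by 0.45 (adjusted over the list alone, 1 rose). In the mesenchymal transition list 2 rose and 3 fell, also when adjusted over the list alone, with Cdh2, encoding N-cadherin, higher by 0.65 and Zeb2 at -0.58. The others, named after their values were seen, were Fn1, which rose, and Snai2 and Vim, which fell. Of 19 luminal epithelial markers 2 rose and 2 fell (adjusted over the list alone, 3 and 2): Foxa1 rose by 0.34, while the keratin gene Krt19 fell from 142 ± 35.5 to 62.0 ± 22.2 CPM. Krt7 rose and Muc1 fell, both named after their values were seen.

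Of 24 proliferation genes, 3 fell, also when adjusted over the list alone, Cdc20 by 0.25 and Ccnb1 by 0.19 on the log2 scale and, named after its value was seen, Mcm5 by 0.19. In the hypoxia and glycolysis list Car9 and Gapdh rose by 0.29 and 0.14 (adjusted over the list alone, 3 rose). The calls of Ccnb1 and Gapdh ended when any of 5 and of 13 tumours was left out (edgeR BH-adjusted p up to 0.0587 and 0.0871). No member passed in the lists for MHC class I presentation (19 measured), oxidative phosphorylation (25), endoplasmic reticulum stress (16), endothelial cells (16) and milk proteins (3), also when adjusted over each list alone. The milk protein list had a median of 0.03, a mean of -0.13 and an upward camera direction (adjusted p = 0.844).

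Marker levels per tumour differed between the groups for 4 of the 15 cell type lists. The count was 9 without EV 1, 1 without p95HER2 1, 2 without p95HER2 2, and 7 with members scaled to SD 1. The macrophage level was 5.23 ± 0.30 in EV and 4.71 ± 0.33 in p95HER2 tumours (exact permutation test, BH-adjusted p = 0.0182). The adipocyte level was 2.48 ± 0.53 and 1.61 ± 0.40 (exact permutation, adjusted p = 0.0165), the keratinocyte level 2.40 ± 0.67 and 1.81 ± 0.26 (exact permutation, adjusted p = 0.0182), and the difference in cytotoxic level was -0.68 (exact permutation, adjusted p = 0.0365). T cell, B cell and basal epithelial levels did not pass (exact permutation, adjusted p = 0.0582, 0.0591 and 0.0591). Endothelial levels were 4.10 ± 0.23 and 3.99 ± 0.21, luminal epithelial levels 6.22 ± 0.15 and 6.24 ± 0.11, and skeletal muscle levels, which varied most, 7.29 ± 1.58 and 6.49 ± 0.96. The macrophage call ended without p95HER2 1, the keratinocyte call without p95HER2 1 or 2, and the cytotoxic call when any of 10 tumours was left out. Without EV 1, the highest EV tumour, the difference in keratinocyte level was -0.38 in place of -0.58 and still passed (exact permutation, adjusted p = 0.00987).

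**Figure D3:**
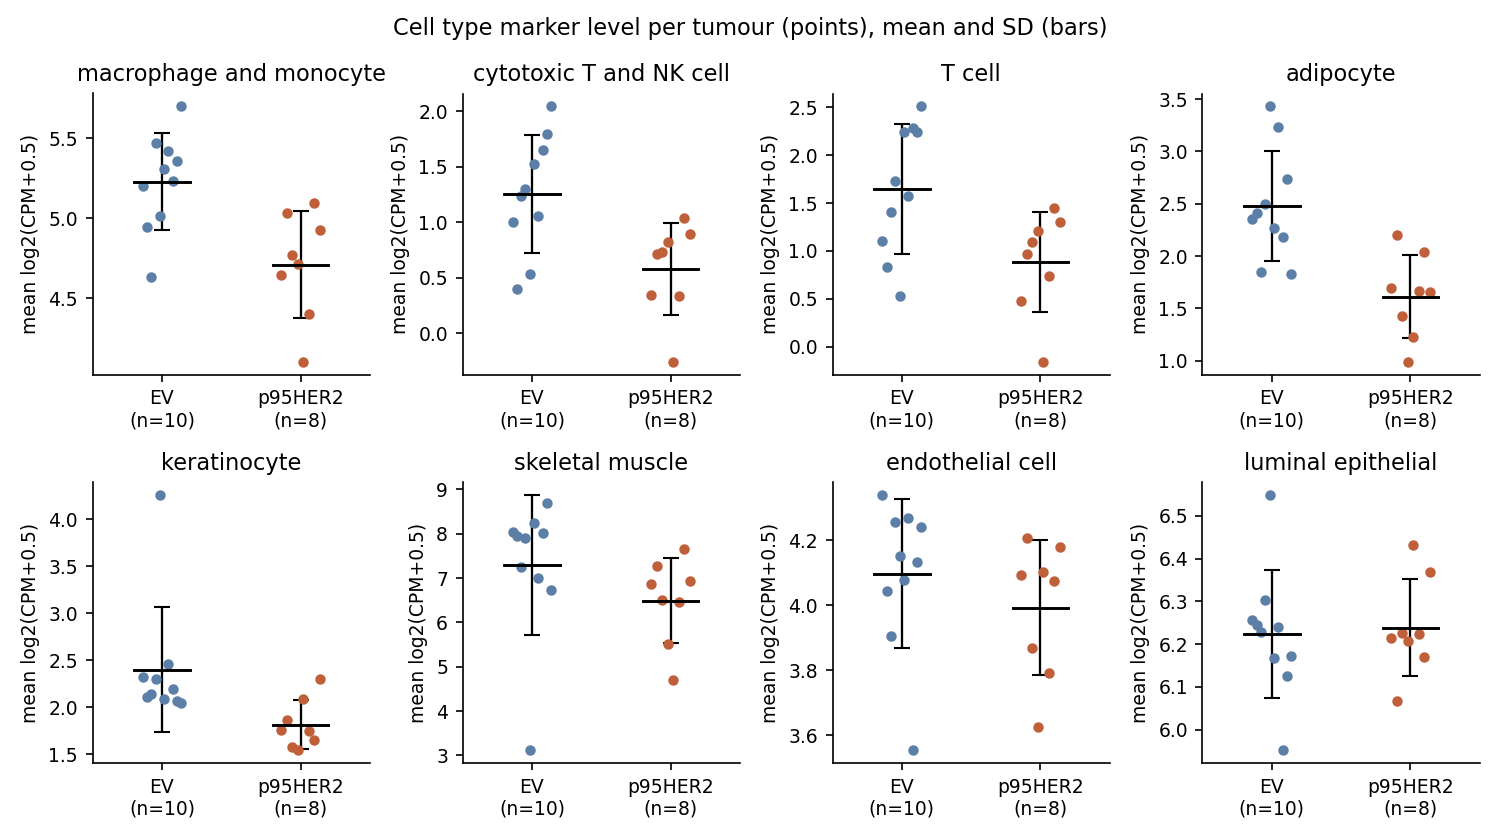
Level of 8 cell type marker lists in each tumour, as mean log2(CPM + 0.5) over the members; points are tumours (EV n = 10, p95HER2 n = 8), horizontal bars means and error bars SD. The macrophage level averaged 5.23 in EV and 4.71 in p95HER2 tumours, and 1 EV tumour lay apart in the keratinocyte and skeletal muscle panels.

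The changed genes were unevenly spread over the genome, a feature examined after the data were seen. Of 12945 genes of the autosomes and chromosome X with a mean log2 CPM of at least 1, chromosome 5 held 857, of which 219 changed (25.6%), 162 higher and 57 lower, against 10.4% of those on the other chromosomes. Of the genes on chromosome 5, those between 20 and 50 Mb (190 genes) and between 130 and 150 Mb (203 genes) had a median log2 fold change of 0.16, and 276 genes between 100 and 130 Mb had a median of -0.09. Of 12 windows on chromosome 5, 8 differed between the groups (exact permutation test with BH adjustment), as did 34 of 219 windows over all chromosomes. On chromosome 11, 123 genes between 110 and 120 Mb had a median of 0.15; Erbb2 lies outside that stretch.

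**Figure D4:**
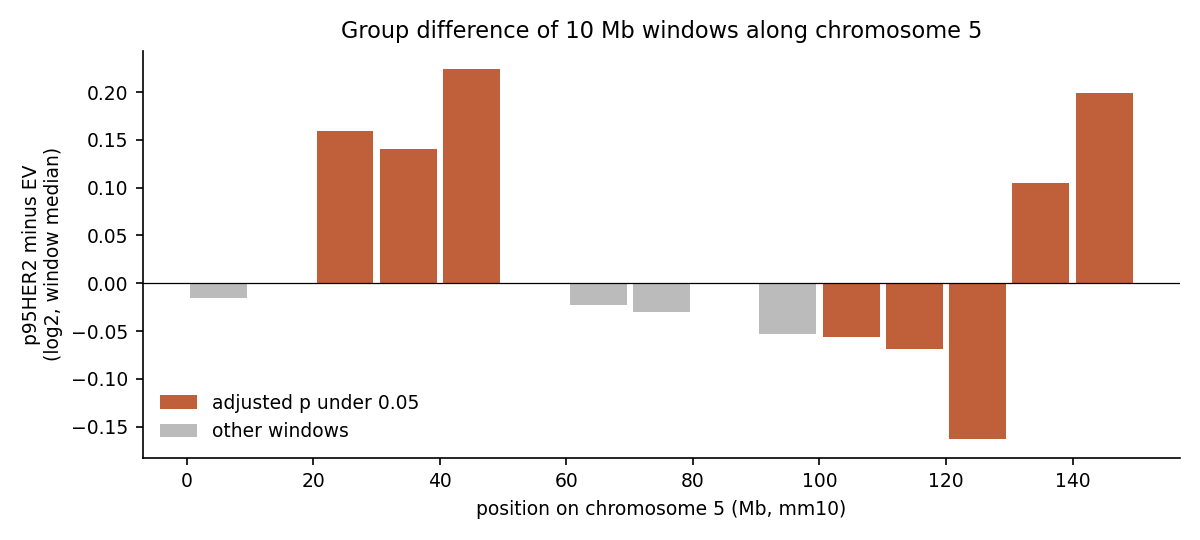
Difference between p95HER2 (n = 8) and EV (n = 10) tumours in the median log2 expression of the genes in each 10 Mb window of chromosome 5 (horizontal axis, Mb in mm10); bars are windows, coloured where the exact permutation test passed. Windows between 20 and 50 Mb and between 130 and 150 Mb were higher, and those between 100 and 130 Mb lower; positions without a bar had fewer than 20 expressed genes.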

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

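A tumour is described here where its gap to the nearest tumour of its own group was large for the range of the group (gap divided by range above the 95% critical value). Of 342 groups of values tested, 22 had such a tumour, where chance gives about 17.1, so single cases carry little weight; 11 of the 22 lay in EV 1.

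In EV 1 the skeletal muscle level was the lowest (gap over range 0.649), and so were Ttn (0.671), Neb (0.63), Tnni2 (0.622) and Atp2a1 (0.663). The same tumour had the highest keratinocyte level (0.814), basal epithelial level (0.703) and values of Dmkn (0.584), Fosl1 (0.644), Mmp10 (0.653) and Cd44 (0.507). Its skeletal muscle level was 3.12 against 6.73 in the next EV tumour.

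EV 7 had the highest Oasl1 (0.501), Cd274 (0.477) and Havcr2 (0.482) and the lowest Lamb3 (0.548), and EV 3 had the lowest Ms4a7 (0.522). Prl2c3 was highest in EV 5 (1), the EV tumour that held its single count. In p95HER2 8 the ERK output level (0.622), the endoplasmic reticulum stress level (0.606) and Alas2 (0.6) were the highest of the group. Ccnb1 was highest in p95HER2 7 (0.618) and Pmepa1 in p95HER2 4 (0.594).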

How the results depend on the processing

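The skeletal muscle covariate, the joint removal of EV 1 and p95HER2 4, thinning and the removal of chromosome 5 genes were chosen after seeing the data. The number of changed genes stayed within 1.5 times of 1743 under RLE scaling (1751), library totals (1718), no filter (1352), a 1 CPM filter (1694), DESeq2 (2367), voom (2338), the epithelial (1510) and muscle (1798) covariates, the joint removal (1866), thinning (1731) and removal of chromosome 5 (1470). No scaling moved the median of all genes beyond -0.03. With each tumour left out it ranged from 1289 to 2331, the higher genes from 792 to 1201 and the lower genes from 489 (without p95HER2 2) to 1130. Of 72 called named genes, 56 kept their call with each tumour left out, 34 with the immune covariate, 53 with the epithelial covariate, 15 against a fold of 1.5, 60 with no filter, 65 with the muscle covariate, 69 with the joint removal and 70 with voom; under the other gene-level settings no called named gene that was tested lost its call. Without p95HER2 1, whose tag number stands apart, 1313 genes changed. Depth limits the genes near 0.

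Testing against a fold of 1.5 left 52 genes (43 higher, 9 lower), since it asks for a larger effect. The immune covariate left 475 genes (334 higher, 141 lower) and gave 11 lists higher and 3 lower, and it adjusts the immune lists for themselves. Directions of lists here are those of camera, and the value in parentheses after a list is its median, whose sign can differ. The direction turned for interferon gamma (0.15), MHC class I (0.14), MHC class II (0.30), dendritic cells (0.15) and luminal epithelial (-0.0905), and for mesenchymal transition (-0.0741) and milk protein (0.0542), whose medians kept their sign. Of these, interferon gamma, MHC class I and MHC class II were then called higher at the preset correlation (camera adjusted p = 0.00965, 0.000139 and 0.00932). An estimated correlation was not run with a covariate. Calls ended for type I interferon (-0.0758), checkpoint (-0.12), sterol synthesis (-0.0193), T cell (-0.21), cytotoxic (-0.25), B cell (-0.12), fibroblast (-0.0607) and skeletal muscle (-0.68). The genes Ciita (0.11), Cd274 (0.13), H2-T23 (0.0830), H2-Ob (0.0925), H2-Oa (0.0509) and H2-Ab1 (0.28), not called in the first place, changed sign.

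The epithelial covariate left 2 lists higher and adjusts the epithelial lists for themselves. Calls ended for HER family (0.0902), interferon gamma (-0.17), MHC class II (-0.35), TGF-beta (-0.00772), sterol synthesis (0.00678), basal epithelial (0.24), skeletal muscle (-0.27) and erythroid (0.41), and MHC class I (0.00816), milk protein (-0.0979) and luminal epithelial (0.0195), the last with a median of unchanged sign, turned direction. The muscle covariate left 8 lists lower: HER family (0.0844), interferon gamma (-0.21), MHC class II (-0.25), sterol synthesis (-0.0392), fibroblast (-0.15) and erythroid (0.77) lost their calls, and luminal epithelial (-0.0351) and milk protein (-0.11) turned direction, as did MHC class I (-0.00317) and skeletal muscle (-0.0406), which is adjusted for itself, with medians of unchanged sign. The joint removal turned milk protein (-0.24). Without chromosome 5 genes HER family (0.0658), interferon gamma (-0.31) and sterol synthesis (-0.0681) were not called, and library totals ended sterol synthesis (-0.0826). Camera with an estimated correlation called 0 lists higher and 0 lower, with adjusted p = 0.418 for HER family, ERK output, invasion, TGF-beta, basal epithelial, cytotoxic, B cell, macrophage, adipocyte and keratinocyte, 0.438 for checkpoint and T cell, 0.476 for type I interferon, 0.557 for erythroid, 0.616 for fibroblast, 0.657 for MHC class II and 0.686 for interferon gamma, sterol synthesis and skeletal muscle (smallest unadjusted p 0.0507, for macrophage). Fry called 5 higher and 4 lower; its adjusted p was 0.103 for type I interferon, 0.390 for interferon gamma and sterol synthesis, 0.285 for MHC class II, 0.0634 for checkpoint, 0.0714 for T cell, 0.0532 for cytotoxic, 0.195 for fibroblast, 0.365 for skeletal muscle and 0.143 for erythroid. Members scaled to SD 1 gave 7 differing marker levels.

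With each tumour left out, lists higher ranged from 3 to 6 and differing marker levels from 1 to 9. List medians ranged from 0.0572 to 0.19 for HER family, 0.0633 to 0.14 for TGF-beta, 0.37 to 1.11 for erythroid, -0.12 to -0.0501 for sterol synthesis, -0.46 to -0.19 for interferon gamma, -0.68 to -0.27 for MHC class II, -1.27 to -0.91 for skeletal muscle, -0.0313 to 0.00117 for oxidative phosphorylation, 0.00575 to 0.0623 for luminal epithelial and -0.18 to 0.32 for milk protein. Marker level differences ranged from -0.0156 to 0.0509 for luminal epithelial and -0.0277 to 0.22 for milk protein. Except where the alternative's construction is named, the cause was not tested.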

Other observations

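The genes of the next 2 sentences were chosen after their values were seen, and the tests of a copy number difference between the injected populations, of a copy number state that varies between tumours, of host cells of every kind and of the share of epithelial cells were chosen only after the result was seen. Beside Hmga2, the related chromatin gene Hmga1 rose from 34.7 ± 4.28 to 60.4 ± 21.7 CPM and Igf2bp2, an mRNA-binding protein gene, from 4.48 ± 0.905 to 10.2 ± 2.65 CPM. Col7a1, which encodes the collagen of anchoring fibrils, rose from 6.44 ± 1.53 to 26.6 ± 19.7 CPM, Wnt7b by 1.59 on the log2 scale, and Spp1, which encodes osteopontin, from 395 ± 174 to 966 ± 436 CPM (SD, n = 10 and n = 8).

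The number of changed genes was set against other splits of the 18 tumours into groups of 8 and 10. Of 100 splits drawn, the real one included, 1 called as many genes. The real split called 1743, and the highest of the other splits called 0 (edgeR quasi-likelihood, BH). A random split of these tumours thus seldom gives such a count, and 100 splits resolve no share below 1 in 100. The other splits mixed the EV and p95HER2 tumours, which widens the spread within their groups and lowers their counts. The splits cannot test a factor that runs along the group labels.

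The raised parts of chromosome 5 were weighed against technical trends. A correction for GC content and exon length left their median log2 fold change at 0.173 against 0.161 before, and with skeletal muscle and immune levels as covariates it was 0.118, so neither trend accounts for the whole shift. Immune cells may account for part, since the level of these parts followed cytotoxic, T cell and macrophage marker levels among EV tumours. No relation with endothelial, fibroblast, skeletal muscle or adipocyte levels passed there. A fixed copy number difference between the injected cell populations was predicted to place all 8 p95HER2 tumours outside the EV range. It cannot be told apart, because 5 lay above that range in the raised parts, where EV tumours spread from -0.12 to 0.14, and 7 lay below it in the lowered part. All 8 lay outside it in 4 of 24 stretches, 3 on chromosome 1 and 1 on chromosome 8. The stretches were built from windows called between the same groups, which favours such separation. The median changes were 6.1%, 4.4% and 6.0% on chromosome 1 and -6.6% on chromosome 8. The prediction also leaves out host cells, whose varying share could make the ranges overlap. A copy number state that varies between tumours may account for the spread among EV tumours, as may a varying share of immune cells. Over the 10 EV tumours the 2 raised stretches rose and fell together (Spearman rho 0.964, Pearson r 0.95), a relation seen before its test was written. The rho lay above 99.99% of window pairs on different chromosomes. That comparison is unequal, because the stretches held 190 and 203 genes and the single windows as few as 20, whose medians are noisier. The relation was found and tested on the same data, no DNA was analysed here, and a coordinated regional change of expression stays open.

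Over the 10 EV tumours the level of the raised stretches was lower where the cytotoxic marker level was higher (Pearson r -0.868, permutation p = 0.00128, adjusted p = 0.0384; Spearman rho -0.879, permutation p = 0.00177, adjusted p = 0.0443; 30 relations). Without the 2 tumours farthest from the median r was -0.701. The T cell level (rho -0.855, permutation p = 0.00295, adjusted p = 0.0443) and the macrophage level (rho -0.830, permutation p = 0.00457, adjusted p = 0.0457) passed by rho, but not by Pearson's r (-0.788, permutation p = 0.00758, and -0.764, permutation p = 0.00966; adjusted p = 0.0725 for both), which was -0.658 and -0.637 without the same 2 tumours. No other list passed over the EV tumours, although r was -0.769 for dendritic cells (permutation, adjusted p = 0.0725). For endothelial, skeletal muscle, adipocyte and fibroblast levels r was -0.092, -0.207, 0.240 and -0.374 (permutation, adjusted p = 0.929 for each). Over the 8 p95HER2 tumours no list passed, and r with the cytotoxic level was -0.187 (permutation p = 0.675, adjusted p = 0.929) and rho -0.167 (permutation p = 0.705, adjusted p = 0.846). Whether the relation with the cytotoxic level differs between the groups was not tested.

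Of the sources weighed for the lower immune lists in p95HER2 tumours, a smaller share of host cells of every kind would lower macrophage and endothelial markers alike, and the macrophage level fell by 0.41 more than the endothelial level (exact permutation p = 0.0108, adjusted p = 0.0433 over 4 contrasts). Endothelial cells were the only reference used. Other levels differed by at least as much as macrophage (-0.52): adipocyte by -0.87, skeletal muscle by -0.81 and keratinocyte by -0.58. Fibroblast and dendritic cell levels differed by -0.26 and -0.29, while neutrophil (0.21) and erythroid (0.64) levels were higher. The macrophage and endothelial levels thus did not fall alike, but the contrast cannot decide on a loss shared with other host cells. For lymphocytes a smaller share of host cells of every kind cannot be told apart, because the differences to the endothelial level for T cell (-0.66, exact permutation p = 0.0623), cytotoxic (-0.57, p = 0.0455) and B cell levels (-0.71, p = 0.0486) did not pass after adjustment (adjusted p = 0.0623 for each). After thinning to the smallest total, 8 of 8 immune lists called by camera with the preset correlation were still called lower. Totals ran only from 32686558 to 38464541 counts before thinning, so it changed depth little and a change of calls was unlikely. Thinning equalises depth only and cannot test a difference in handling that followed library total, so library size is not decided by it. None of the 8 was called with an estimated correlation, even without thinning (camera adjusted p from 0.418 to 0.686). With the skeletal muscle level as a covariate 6 of 8 were still called lower at the preset correlation, so the muscle content of the sample cannot be told apart as a partial source, because interferon gamma and MHC class II lost their calls. A lower content of macrophages in p95HER2 tumours is a possible reading. A loss shared with other host cells and a lower expression of these genes per cell stay open.

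By thresholds set after the data were seen, 10 genes were near 0 in EV tumours (mean under 0.1 CPM) and above 0.25 CPM in all 8 p95HER2 tumours with a mean above 1 CPM, and 0 genes showed the mirror pattern. They were Prl2c3, Gpr149, Aqp8, Il24, Tmprss11e, Dynap, Wnt7a, Klk6, Pbp2 and Gm20744; Il24 had 3 counts over all EV tumours and 968 over the p95HER2 tumours, a ratio of 438 with a counting interval from 150 to 2129. Over the 8 p95HER2 tumours their mean level rose with Erbb2 (Spearman rho 0.905, exact permutation p = 0.00456, adjusted p = 0.00913; Pearson r 0.875, exact permutation p = 0.00432, adjusted p = 0.00863; r 0.844 without the 2 farthest tumours; 2 relations computed), which would be consistent with a response graded by Erbb2. The other relation, with the luminal epithelial level, did not pass (rho -0.19, exact permutation p = 0.665, adjusted p = 0.665; r 0.120, exact permutation p = 0.786, adjusted p = 0.786; r 0.262 without the 2 farthest tumours), and 0% of them lay in the shifted stretches, which hold 17.2% of all tested genes. With only 10 genes, the absence from these stretches decides nothing about copy number. A differing share of cells that express p95HER2 would give the same relation with Erbb2 and was not tested.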
